A study of Mus musculus with 9 samples.

How the data were processed

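RNA of 9 pooled samples of sorted mouse retinal cells was measured, 3 for each of 3 groups: GFP-positive and GFP-negative cells of rhoEGFP pups at postnatal day 4 and GFP-positive cells of pNestin-GFP pups at postnatal day 0. Per the labels, the background was C57BL/6J-129/Ola and each replicate pooled the retinae of 6 to 8 mice. Per the labels' protocols, RNA was isolated with Qiagen RNeasy Mini columns and biotin-labelled cRNA was made from 200 ng of total RNA with an Ambion MessageAmp kit. The values deposited by the authors are on the log2 scale and came from RMA, per the submitters' processing notes; its version is not given in the sources used here. RMA corrects background, quantile-normalizes probe intensities between arrays and summarises each probe set, which compresses low signals, so that folds of genes near the lower end are understated. The table has no detection calls, and scan batches are not given in the sources used here.

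The table held 45101 probe sets, 64 of them controls. Of the 45037 others the annotation tied 34945 to 1 gene symbol and 932 to several, and did not list 9160 with a gene; the symbols of 34741 probe sets were looked up by Entrez ID. Genes were taken only from probe sets with 1 symbol, and a gene with several (9009 genes) was represented by the probe set with the highest mean log2 value over the 9 arrays, which gave 18194 genes. The 10092 probe sets without a single symbol were tested separately and are not named. The values of all 9 arrays were used, and no array was a copy of another. Between 2 replicates of a group at most 1022 (rhoGFP-positive), 1358 (rhoGFP-negative) and 838 (nestinGFP-positive) of the 45101 probe sets held exactly equal values. Within groups the median absolute log2 difference between 2 arrays ran from 0.122 to 0.255.

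Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a single fit of all 9 arrays with 3 group means, so that the groups share an estimate of the spread. Adjusted p values follow Benjamini and Hochberg over the 18194 genes of a comparison. A gene was called at an adjusted p below 0.05 and an absolute log2 difference of at least 1. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 21 lists that had at least 5 measured members. The 23 lists, with 465 different symbols, 433 of them measured, were written before the data were examined. They cover rods, photoreceptor transcription factors, cones, the photoreceptor synapse, cilium transport, progenitors and glia, neurogenesis, the cell cycle, amacrine, ganglion, horizontal and bipolar cells, Müller glia, astrocytes, endothelial and mural cells, microglia, pigment epithelium, erythrocytes, lens, surface antigens, stress, glycolysis and sex-linked genes. Figures were drawn with matplotlib 3.10.9.

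The groups and tests, the alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule named the 6 largest called differences each way in each of the 2 comparisons of the rhoGFP-positive fraction and the 3 largest each way in the third comparison, among genes whose arrays did not overlap between groups and passing over clone and model names. It added the 2 largest called members of each list with at least 3 called, surface antigens called in both comparisons of the rhoGFP-positive fraction, and Nrl, Crx, Nt5e, Nes and Opn1sw whatever their result; other genes fixed with these are not analysed here. Further members named beside counts were chosen after their values were seen.

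Each replicate number occurs in all 3 groups, and the labels do not say that a number marks a shared pool. Over genes, the deviations from the group means of same-numbered arrays correlated at 0.62, 0.45 and 0.45 between the rhoGFP fractions, and at 0.54, 0.16 and 0.23 between the rhoGFP-negative and nestinGFP-positive groups, so the numbers were taken to pair the arrays in these 2 comparisons, from the data and not from the design. Arrays of different numbers correlated at -0.49 to 0.074 between the rhoGFP fractions and at -0.39 to 0.22 between the rhoGFP-negative and nestinGFP-positive groups. In the latter, rhoGFP-negative replicate 2 stood at 0.22 with nestinGFP-positive replicate 3, above its 0.16 with replicate 2. Pairing there is weak beyond replicate 1, and the groups come from different lines and ages. The alternatives were other normalizations of the deposited values (common median, quantile, cyclic loess), the mean of all probe sets of a gene, leaving out _x_at and _s_at probe sets, leaving out genes below the 40th percentile of mean signal, only the 6 arrays compared, the replicate block, eBayes with trend and robust settings, other thresholds, camera with an estimated correlation, fry, and leaving out each array in turn.

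The steps were tested on simulated data in 20 runs of normal noise around the mean of each of the 18194 genes, with its moderated spread and 200 genes changed. Of genes changed by a log2 difference of 1, 1.5, 2 and 3, the fit called 47.7%, 96.5%, 99.0% and 100% in the comparison of the rhoGFP fractions. The shares were 48.8%, 96.7%, 99.3% and 100% in that of the GFP-positive fractions, and 1.35% and 1.2% of the calls were false. Of the genes changed by 1, 87.3% and 87% passed the adjusted p in the same order of comparisons. The required difference of at least 1 thus limited their calls. With no change simulated, at most 1 gene was called in a run, and camera put 2% of random lists below p 0.05. The noise was drawn separately for each gene and array, so the runs held no correlation between genes and no pairing of arrays. They cannot show the error rate of camera on lists of correlated genes.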

Results

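Gene expression was measured on 9 Affymetrix arrays of RNA from mouse retinal cells separated by fluorescence-activated cell sorting. Pups of the rhoEGFP line, a reporter line for rod photoreceptors, gave a GFP-positive and a GFP-negative fraction at postnatal day 4 (P4). Pups of the pNestin-GFP line, a reporter line for the progenitor filament nestin, gave a GFP-positive fraction at postnatal day 0 (P0). Each group held 3 biological replicates, and each replicate pooled the retinae of 6 to 8 mice. The median log2 value of all probe sets lay between 6.08 and 6.17 on the 9 arrays, and 18194 genes were tested. The number of arrays limits the precision, with a median standard error of 0.14 log2 units for a difference between groups.

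The first principal component held 72.6% of the variance and set the rhoGFP-positive arrays, with scores of -71.5 to -58.5, apart from the 6 others, with scores of 6.35 to 51.1. The second component held 11.7%. Array correlations ran from 0.985 to 0.996 within groups, and the lowest between groups, 0.918, was between a rhoGFP-positive and a nestinGFP-positive array. The actin control probe sets, a sign of RNA integrity, gave a 3' minus 5' log2 difference of 0.91 ± 0.064 (SD, n = 3) in the rhoGFP-positive, 0.65 ± 0.021 in the rhoGFP-negative and 0.67 ± 0.30 in the nestinGFP-positive fraction. The mean of 3 control probe sets for 18S ribosomal RNA was 13.6, 13.6 and 12.1 on the replicate 1 arrays of the rhoGFP-positive, rhoGFP-negative and nestinGFP-positive groups, and between 9.65 and 10.4 on the 6 other arrays.

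**Figure D1:**
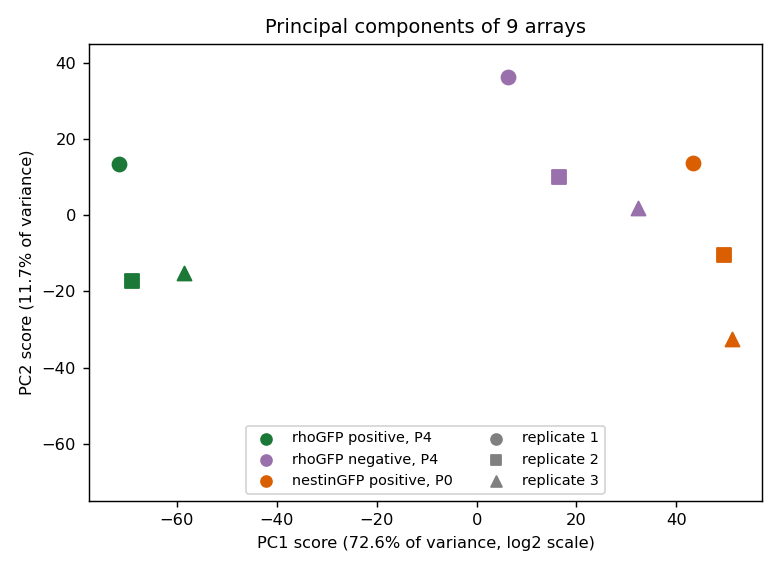
Scores of the 9 arrays on the first component (horizontal axis, 72.6% of the variance) and the second (vertical axis, 11.7%), computed on log2 values; each point is an array, colour gives the group and shape the replicate number. The rhoGFP-positive arrays lie at -71.5 to -58.5 on the first component and the other arrays at 6.35 to 51.1.

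The comparison of the 2 rhoGFP fractions at P4 addresses which transcripts, including those of surface proteins that an antibody could reach, mark young rods within the retina of 1 age. In the rhoGFP-positive cells limma called 29 of 33 rod phototransduction genes higher, and 20 of 23 progenitor, 12 of 14 neurogenic and 31 of 51 cell cycle genes lower. Camera called these 4 lists at its preset correlation and none of them with an estimated correlation (adjusted p = 0.0647, 0.0749, 0.0647 and 0.315 in the same order). The rod cyclic-nucleotide channel subunit Cnga1 stood at 11.1 ± 0.18 (log2, SD, n = 3) against 6.15 ± 0.53, a 30.5-fold difference, and the retinol dehydrogenase Rdh12 was 23.7-fold higher. The chemokine receptor Cxcr4 was 8.27-fold lower, and the ribonucleotide reductase subunit Rrm2, needed for DNA synthesis, was 7.67-fold lower. In all, limma called 656 genes higher and 1332 lower at an adjusted p below 0.05 and at least a 2-fold difference, which is 10.9% of the genes tested.

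The 6 genes with the largest rise were Pax7 (log2 difference 5.43 ± 0.40 SE, limma adjusted p = 1.41e-05), Cnga1 (4.93 ± 0.25, 2.64e-06), Ppargc1b (4.85 ± 0.28, 4.64e-06), Mpp4 (4.71 ± 0.15, 6.57e-07), Rdh12 (4.57 ± 0.26, 4.64e-06) and Tdrd7 (4.39 ± 0.28, 6.81e-06). Pax7 encodes a paired-box transcription factor, Ppargc1b a transcriptional coactivator of mitochondrial genes, Mpp4 a scaffold protein of photoreceptor terminals and Tdrd7 a Tudor-domain protein of RNA granules. The largest falls, after Cxcr4 (-3.05 ± 0.38) and Rrm2 (-2.94 ± 0.41), were in the adhesion gene Cdh11 (-2.89 ± 0.24), the guidance receptor Robo1 (-2.88 ± 0.28), Lhfp (-2.86 ± 0.31) and Dkk3 (-2.84 ± 0.19). The call stayed but the difference shrank to -1.07 in Robo1 with the mean of its probe sets and to -1.81 in Rrm2 without _x_at and _s_at probe sets.

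Of 33 measured genes of rod phototransduction and the outer segment, 29 rose and 0 fell, with a median log2 difference of 2.16 (limma camera adjusted p = 3.08e-22; adjusted p = 0.0647 with an estimated correlation). The 4 members without a call included Abca4, the outer-segment retinoid transporter, at 0.05, and Guca1b at 0.53. Genes of the photoreceptor synapse rose in 13 of 21, with a median of 1.30 (camera adjusted p = 4.37e-10; adjusted p = 0.0647 with an estimated correlation). Among them were the vesicular glutamate transporter Slc17a7 (3.09 ± 0.17) and the calcium channel Cacna1f (3.00 ± 0.24). Genes of cilium transport rose in 13 of 32, with Bbs7 (2.18 ± 0.13) and Bbs5 (2.10 ± 0.20) of the BBSome leading, and a median of 0.82 (camera adjusted p = 5.04e-12). With the mean of its probe sets Bbs7 was at 1.35. The cilium list alone kept its call with an estimated correlation (adjusted p = 0.0038).

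Among 13 photoreceptor transcription factors 4 rose, with a list median of 0.71 (camera adjusted p = 0.00185; adjusted p = 0.288 with an estimated correlation): Ankrd33 (3.36 ± 0.17), Samd11 (2.07 ± 0.18; 1.28 with the mean of its probe sets), Samd7 (1.72) and Nrl (1.06 ± 0.27). Nrl, the leucine-zipper factor that directs rod fate, stood at 13.6 ± 0.055 against 12.6 ± 0.33 (limma adjusted p = 0.0185). Its adjusted p was 0.0723 without replicate 3 of the rhoGFP-negative group and 0.0603 and 0.0549 without replicates 2 and 3 of the rhoGFP-positive group. Crx, the homeobox factor shared by rods and cones, was not called (0.71 ± 0.29, limma adjusted p = 0.114). Cone genes rose in 3 of 13, Rxrg (1.89 ± 0.17), Cngb3 (1.56 ± 0.12) and Kcne2 (1.01), with a list median of 0.40 (camera adjusted p = 0.00251; adjusted p = 0.0647 with an estimated correlation). The short-wave cone opsin Opn1sw was not called (0.58 ± 0.34, limma adjusted p = 0.289), and its arrays overlapped between the fractions.

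Genes of progenitors and glia fell in 20 of 23, with a median of -2.01 (camera adjusted p = 1.17e-14; adjusted p = 0.0749 with an estimated correlation), led by the growth factor Fgf15 (-2.54 ± 0.47) and the Notch target Hes5 (-2.48 ± 0.22). Neurogenic genes fell in 12 of 14, with Olig2 (-2.59 ± 0.21) and Dll3 (-2.39 ± 0.15) in front and a median of -1.67 (camera adjusted p = 8.77e-09; adjusted p = 0.0647 with an estimated correlation). Of 51 genes of the cell cycle and replication 31 fell, or 36 when adjusted over the list alone, with a median of -1.46 (camera adjusted p = 2.44e-13; adjusted p = 0.315 with an estimated correlation). Mcm3, a subunit of the replicative helicase, fell by 2.42 ± 0.35, and by over 1.5 times less with the mean of its probe sets (limma adjusted p = 0.00148). The median of the cell cycle genes was 9.71 on rhoGFP-negative replicate 3 against 8.12 and 8.02 on replicates 1 and 2, and 7.66 on rhoGFP-positive replicate 3 against 7.19 and 7.09. Nes, which encodes nestin, was not called (-0.56 ± 0.18, limma adjusted p = 0.0547).

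Among markers of other retinal neurons, amacrine genes fell in 11 of 17, with a median of -1.76 (camera adjusted p = 0.000199; adjusted p = 0.288 with an estimated correlation), among them Ptf1a (-2.37 ± 0.35) and the inhibitory vesicular transporter Slc32a1 (-2.35 ± 0.26; -0.57 and no call with the mean of its probe sets). Ganglion cell genes fell in 9 of 21, or 10 adjusted over the list alone, with Ebf3 (-2.59 ± 0.37) and Ebf1 (-1.90 ± 0.32) leading and a median of -0.58 (camera adjusted p = 0.002; adjusted p = 0.251 with an estimated correlation). Bipolar cell genes went both ways (camera adjusted p = 0.319, and 0.0421 without dim genes): Lhx4 (-2.37 ± 0.18), Irx5 (-2.36 ± 0.28) and Irx6 (-1.09) fell, while Prkca (1.51) and Gng13 (limma adjusted p = 0.00196) rose. Of 8 horizontal cell genes, Prox1 (-2.63) and Onecut2 (-1.76) fell, and the list was not called (camera adjusted p = 0.908; median 0.04, mean -0.41).

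Of 10 genes of mature Müller glia, Dkk3 (-2.84 ± 0.19), Gpr37 (-2.79 ± 0.14), Rlbp1 (-2.32) and Kcnj10 (-1.39) fell and Clu (1.05) rose (camera adjusted p = 0.00218; adjusted p = 0.207 with an estimated correlation). Of 20 genes of endothelial, mural and fibroblast cells, Kdr (-2.44 ± 0.18), Col4a1 (-2.03 ± 0.34), Col4a2 (-1.69) and Cldn5 (-1.55) fell, and the list was not called (camera adjusted p = 0.111). It was called lower without dim genes (median -1.62, adjusted p = 0.00644) and with the mean of probe sets (adjusted p = 0.0303). Of 16 microglia and macrophage genes limma called 0, by either adjustment, and 1 had an unadjusted p below 0.05, though the list was (median 0.33, camera adjusted p = 0.0369; adjusted p = 0.55 with an estimated correlation). Their median was 6.56 on rhoGFP-positive replicate 3 against 5.57 and 5.88 on replicates 1 and 2. The list median fell to 0.08, with camera adjusted p = 0.739, without that array. Adjusted p was 0.0971 without rhoGFP-negative replicate 3, 0.0798 with the mean of probe sets and 0.12 without _x_at and _s_at probe sets. Of 11 pigment epithelium genes, Tyrp1 (1.94) and Rgr (1.43) rose (camera adjusted p = 0.0843, and 0.047 without rhoGFP-positive replicate 1). The erythrocyte (adjusted p = 0.345) and lens (adjusted p = 0.708) lists had no called member, with 2 of 5 and 0 of 12 at an unadjusted p below 0.05. The lists of astrocyte and sex-linked genes held 4 measured members each and were not tested; their medians were -0.18 and 0.26.

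Stress genes rose in 5 of 21 and fell in 2, with a median of 0.32 (camera adjusted p = 0.024; adjusted p = 0.51 with an estimated correlation). The rises were in the inducible chaperones Hspa1a (3.62 ± 0.52) and Hspa1b (3.27 ± 0.49) and in Ier3 (2.48), Nr4a1 (1.31) and Junb (1.08); Egr2 (-1.04) and Klf6 (-1.01) fell. Within replicate numbers 1, 2 and 3 the stress median was -0.09, 0.46 and 0.49. The call of the stress list was lost without rhoGFP-positive replicate 3 (adjusted p = 0.052) and without rhoGFP-negative replicate 2 (0.0725) or 3 (0.0777). Glycolysis genes split, with Eno2 (1.87 ± 0.26), Aldoc (1.43) and Hk1 (1.25) higher and 7 of 18 lower, among them Hk2 (-1.78) and Slc16a3 (-1.77), and a median of -0.72 (camera adjusted p = 0.0225; adjusted p = 0.388 with an estimated correlation). That call was lost after cyclic loess (adjusted p = 0.0755) and without dim genes (0.0706). The glucose transporter Slc2a3 was at -2.29 ± 0.30, at -1.13 with the mean of its probe sets, and at -0.14 with no call when probe sets of the _x_at and _s_at kinds were left out. These shifts stood beside the higher actin 3' minus 5' difference of the rhoGFP-positive arrays, 0.91 against 0.65.

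**Figure D2:**
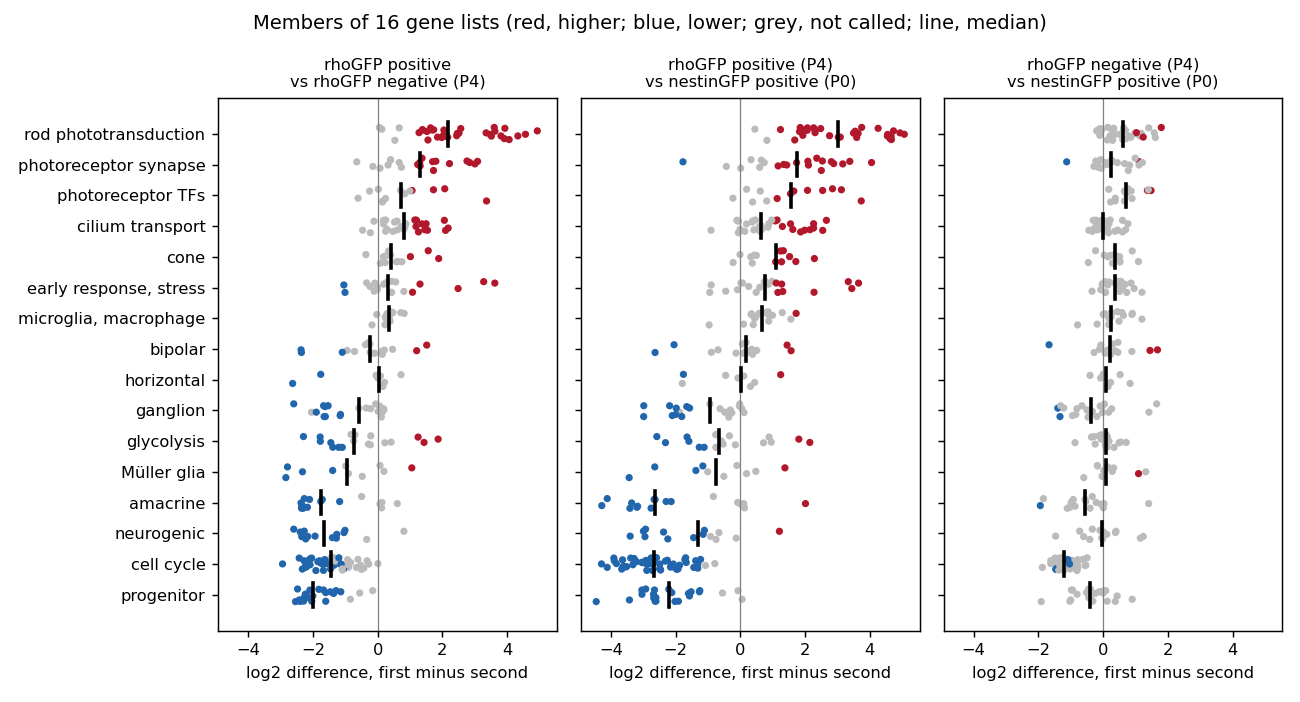
Log2 differences (horizontal axes) of the members of 16 gene lists (vertical axis) in the 3 comparisons; each point is a gene, red where called higher, blue where called lower, grey where not called, and the black line is the list median. Rod phototransduction genes have medians of 2.16, 3.02 and 0.60 from left to right, and cell cycle genes -1.46, -2.66 and -1.22.

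The comparison of rhoGFP-positive cells at P4 with nestinGFP-positive cells at P0 sets rod-reporter cells against younger nestin-reporter cells. The rod phosphodiesterase subunit Pde6b was 30.5-fold higher in the rhoGFP-positive cells, at 12.5 ± 0.046 against 7.53 ± 0.74 (log2, SD, n = 3), and Rdh12 was 33.4-fold higher. The hyaluronan receptor Cd44 was lower, at 3.87 ± 0.12 against 9.57 ± 0.17, where the lower value is a low signal with no detection call, so no fold is given, and the growth factor Fgf15 was lower by 4.46 log2 units. Cell cycle genes fell in 49 of 51 (adjusted p = 0.204 for the list with an estimated correlation). In all, limma called 921 genes higher and 1917 lower, which is 15.6% of the genes tested. Age, reporter line and cell population differ together here, so that their parts cannot be separated.

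The 6 genes with the largest rise were Rdh12 (5.06 ± 0.26 SE, limma adjusted p = 1.46e-06), Pde6b (4.93 ± 0.40), Pax7 (4.90 ± 0.40), Cnga1 (4.73 ± 0.25), Ppp2r2b (4.72 ± 0.59) and Gje1 (4.67 ± 0.28), whose signal in the nestinGFP-positive cells was low, at 2.80. Low signals leave the size and rank of the differences of Gje1 and Cd44 uncertain. The 6 largest falls were in Cd44 (-5.70 ± 0.18, limma adjusted p = 4.47e-07), Fgf15 (-4.46 ± 0.47), Rrm2 (-4.29 ± 0.41), the LIM-homeobox gene Lhx9 (-4.29 ± 0.41), the mitotic kinase Aurkb (-4.12 ± 0.57) and the GABA-synthesis enzyme Gad1 (-4.12 ± 0.50). With the mean of its probe sets Cd44 was at -2.865 and still called. Nrl rose by 2.54 ± 0.27 (limma adjusted p = 7.34e-05) and Crx by 2.07 ± 0.29 (limma adjusted p = 0.000356). Opn1sw was called at 1.09 ± 0.34 (limma adjusted p = 0.0317). The call was lost without replicate 3 of the rhoGFP-positive group (0.78, adjusted p = 0.109), without its replicate 2 (adjusted p = 0.0987), and without replicate 1, 2 or 3 of the nestinGFP-positive group (adjusted p = 0.0595, 0.0642 and 0.0903). It was also lost with the mean of its probe sets, at 0.82. Nes, at -0.55 ± 0.18 (limma adjusted p = 0.0406), was below the 2-fold minimum, while 1 of its 2 other probe sets was called lower.

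Rod phototransduction genes rose in 31 of 33, with a median of 3.02 (camera adjusted p = 4.11e-20; adjusted p = 0.104 with an estimated correlation). Photoreceptor transcription factors rose in 8 of 13, with Ankrd33 (3.73 ± 0.17) and Samd7 (3.12 ± 0.38) in front and a median of 1.55 (camera adjusted p = 6.28e-06; adjusted p = 0.138 with an estimated correlation). Cone genes rose in 7 of 13, among them Rxrg (2.28 ± 0.17) and the cone transducin subunit Gnb3 (1.71 ± 0.26), with a median of 1.09 (camera adjusted p = 0.000545; adjusted p = 0.104 with an estimated correlation). Synapse genes rose in 14 of 21, led by Lrit1 (4.05 ± 0.38) and Slc17a7 (3.38 ± 0.17), while Rims1 (-1.78) fell (median 1.74, camera adjusted p = 9.5e-08; adjusted p = 0.104 with an estimated correlation). Cilium transport genes rose in 12 of 32, with Cep290 (2.66 ± 0.32) and Bbs5 (2.54 ± 0.20) in front and a median of 0.65 (camera adjusted p = 1.04e-07), and this list kept its call with an estimated correlation (adjusted p = 0.0146).

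Cell cycle genes had a median of -2.66, with 50 of 51 lower when adjusted over the list alone (camera adjusted p = 7.22e-21; adjusted p = 0.204 with an estimated correlation). Progenitor and glia genes fell in 20 of 23, among them the eye-field factor Pax6 (-3.43 ± 0.26), with a median of -2.21 (camera adjusted p = 1.48e-12; adjusted p = 0.104 with an estimated correlation). Neurogenic genes fell in 9 of 14, with Atoh7 (-3.41 ± 0.34; -1.96 without _x_at and _s_at probe sets) and Sox11 (limma adjusted p = 5.30e-06) leading, and Insm1 (limma adjusted p = 0.000899) rose (median -1.30, camera adjusted p = 1.37e-06; adjusted p = 0.104 with an estimated correlation). Amacrine genes fell in 11 of 17 and Slc6a9 (2.01), a glycine transporter, rose (median -2.64, camera adjusted p = 1.9e-05; adjusted p = 0.204 with an estimated correlation). Ganglion cell genes fell in 9 of 21, with Dlx1 (-2.99 ± 0.27) and Stmn2 (-2.99 ± 0.33) in front (median -0.94, camera adjusted p = 6.88e-05; adjusted p = 0.138 with an estimated correlation).

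Among the other cell types, Dkk3 (-3.44 ± 0.19), Gpr37 (-2.65 ± 0.14), Kcnj10 (-1.38) and Glul (-1.16) of the Müller list fell and Clu (1.37) rose (camera adjusted p = 0.0305; adjusted p = 0.294 with an estimated correlation). The Müller call was lost without replicate 1 of the nestinGFP-positive group (median -0.48, adjusted p = 0.0684). Col4a1 (-2.93 ± 0.34), Col4a2 (-2.65 ± 0.30), Cldn5 (-2.37) and Kdr (-2.34) fell in an endothelial and mural list that was not called (camera adjusted p = 0.418; median 0.04, mean -0.47). Without dim genes it was called lower (median -2.35, adjusted p = 0.0117). Irx5 (-2.64 ± 0.28) and Car8 (-2.05 ± 0.28; -1.145 with the mean of its probe sets) fell and Gng13 (1.56) and Prkca (1.44) rose among bipolar genes (camera adjusted p = 0.587; median 0.17, mean -0.05). Onecut2 (-1.76) fell and Septin4 (1.24) rose among horizontal genes (camera adjusted p = 0.98; median 0.02, mean -0.25). The microglia list had a median of 0.66 with Tyrobp (1.72) called (camera adjusted p = 0.0135; adjusted p = 0.557 with an estimated correlation). It was 0.29 without rhoGFP-positive replicate 3 (adjusted p = 0.0701). Tyrp1 (2.62) and Rgr (1.85) rose in the pigment epithelium list (camera adjusted p = 0.0436; adjusted p = 0.264 with an estimated correlation). That call was also lost without rhoGFP-positive replicate 2 (0.0565) or 3 (0.0641) or nestinGFP-positive replicate 1 (0.0792). It was lost after cyclic loess (0.0819) and with the mean of probe sets (0.0559) as well. The erythrocyte (adjusted p = 0.688) and lens (adjusted p = 0.704) lists held no called gene, with 0 of 5 and 1 of 12 at an unadjusted p below 0.05.

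Stress genes rose in 8 of 21 and fell in 0, with a median of 0.76 (camera adjusted p = 0.00167; adjusted p = 0.422 with an estimated correlation), led by Hspa1a (3.65 ± 0.52) and the early response gene Ier3 (3.44 ± 0.29). Glycolysis genes fell in 6 of 18, among them Slc2a3 (-2.58 ± 0.30) and the lactate carrier Slc16a1 (-2.32 ± 0.26), and rose in Aldoc (2.14) and Eno2 (1.80), with a median of -0.66 (camera adjusted p = 0.0484; adjusted p = 0.49 with an estimated correlation). That call was lost after cyclic loess (adjusted p = 0.153), without dim genes (0.211) and with only the 6 arrays compared (0.0549). With the mean of probe sets Slc16a1 was at -1.185, and Slc2a3 was at -0.14 with no call without _x_at and _s_at probe sets. The glycolysis call was also lost without rhoGFP-positive replicate 2 (0.0551) or 3 (0.0641), rhoGFP-negative replicate 3 (0.0668), or nestinGFP-positive replicate 1 (0.0837) or 3 (0.106). The actin 3' minus 5' difference stood at 0.91 ± 0.064 (SD, n = 3) in the rhoGFP-positive and 0.67 ± 0.30 in the nestinGFP-positive arrays. The groups overlapped, with nestinGFP-positive replicates 1, 2 and 3 at 0.40, 0.61 and 0.99 and the rhoGFP-positive arrays at 0.85 to 0.97.

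**Figure D3:**
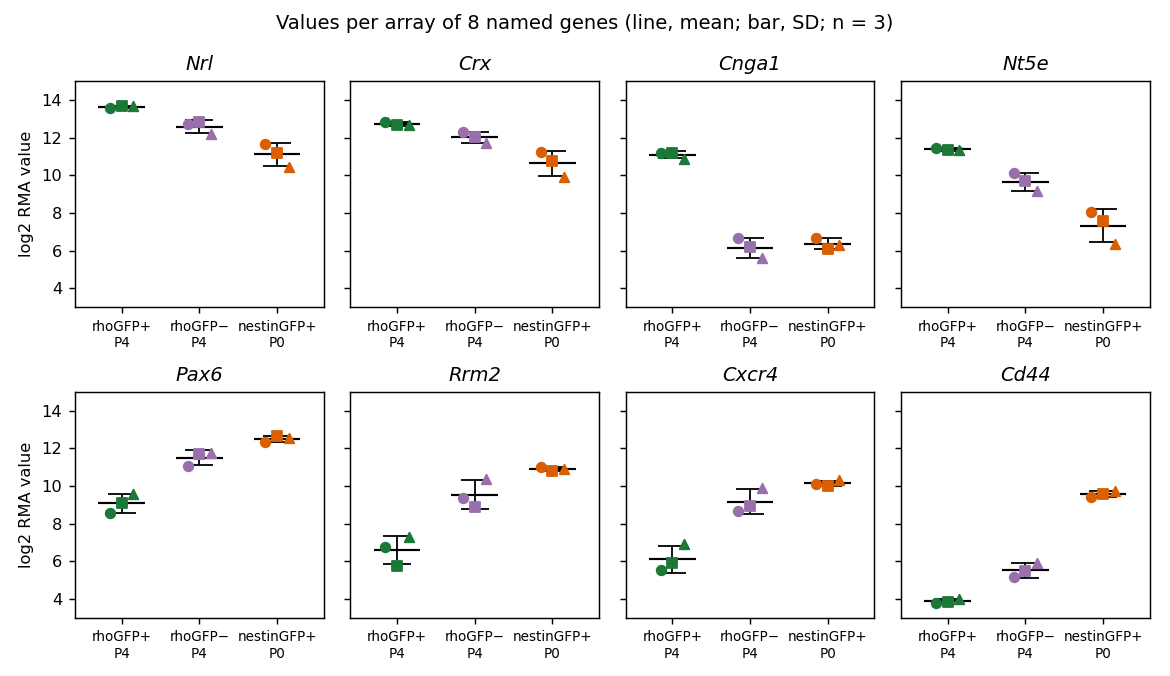
Log2 RMA values (vertical axes) of 8 genes on each array of the 3 groups (horizontal axes); circles, squares and triangles are replicates 1, 2 and 3, the line is the group mean and the bar the SD (n = 3). Cnga1 is at 11.1 in the rhoGFP-positive and 6.15 in the rhoGFP-negative fraction, while Cd44 is at 3.87, 5.51 and 9.57 from left to right.

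Genes that differed in the rhoGFP-positive cells from both other fractions address which transcripts mark these cells against their sorted counterpart and against younger cells. In both comparisons 586 genes were higher, Pax7, Cnga1 and Rdh12 among them, and 1209 were lower, with Cxcr4 and Rrm2 among them. Independent lists of these sizes would share 33.2 and 140 genes. Unchanged groups simulated against shared arrays shared 0, but at most 1 gene was called in such a run, so this value sets no level for the observed overlap. Both comparisons use the same 3 rhoGFP-positive arrays, too few to divide, so part of the excess may come from them. Of 54 measured surface antigen genes, 2 were higher in both comparisons: Nt5e, which encodes the ecto-5'-nucleotidase CD73, and Prom1, which encodes prominin. Over all genes tested 586 of 18194 were higher in both, so the share among antigens was near that of all genes.

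Nt5e was at 11.4 ± 0.068 (log2, SD, n = 3) in the rhoGFP-positive, 9.65 ± 0.48 in the rhoGFP-negative and 7.32 ± 0.88 in the nestinGFP-positive cells. It was 3.29-fold higher than in the rhoGFP-negative fraction (1.72 ± 0.39 SE, limma adjusted p = 0.00892) and 16.6-fold higher than in the nestinGFP-positive one (4.05 ± 0.39, limma adjusted p = 3.30e-05). Between the 2 rhoGFP fractions, 0 of its 2 other probe sets were called and 1 had the opposite sign. The mean of its probe sets gave 0.91 and no call there (2.01 and a call against the nestinGFP-positive cells), and without both replicate 3 rhoGFP arrays the difference was 1.48 (limma adjusted p = 0.0838). Prom1, named in the rod list as well, stood at 13.5 ± 0.079, 11.8 ± 0.21 and 11.2 ± 0.17 in the same order, 3.10-fold and 4.80-fold higher in the rhoGFP-positive cells (limma adjusted p = 2.40e-05 and 2.51e-06).

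Antigen genes lower in both comparisons were Cxcr4, Kit, Ngfr, Mcam, Cd9, Pdgfra, Cd24a, Cd200, Nrcam, Ptprf, Fgfr1, Cd44, Notch1 and Cd59a. Against the rhoGFP-negative fraction their log2 differences ran from -3.05 in Cxcr4 to -1.05 in Cd59a, and the receptor tyrosine kinase Kit fell by 2.72 ± 0.19. Against the nestinGFP-positive cells they ran from -5.70 in Cd44 to -1.19 in Cd59a. The whole list was called lower against the rhoGFP-negative fraction, with 15 of 54 lower (median -0.13, camera adjusted p = 0.00185; adjusted p = 0.0647 with an estimated correlation). It was also called lower against the nestinGFP-positive cells, with 17 lower (median -0.25, camera adjusted p = 0.00551; adjusted p = 0.104 with an estimated correlation). Fgfr1 lost both calls without _x_at and _s_at probe sets (-0.46 and -0.62). Cd44 lost that against the rhoGFP-negative fraction (-0.67) and Pdgfra that against the nestinGFP-positive cells (-0.67) with the mean of probe sets. Kit, Ngfr and Nrcam kept both calls with the mean of probe sets, but at differences over 1.5 times smaller (Ngfr at -1.22 and -1.23), and so did Pdgfra against the rhoGFP-negative fraction (-1.03). Cd59a fell short of the 2-fold minimum against the rhoGFP-negative fraction without rhoGFP-positive replicate 3 (limma adjusted p = 0.000739).

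**Figure D4:**
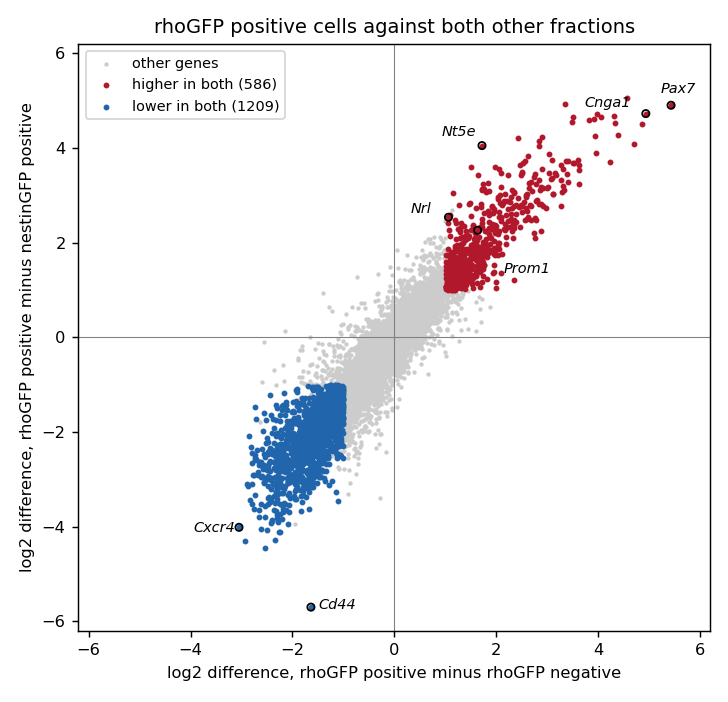
Log2 differences of 18194 genes between rhoGFP-positive and rhoGFP-negative cells (horizontal axis) and between rhoGFP-positive and nestinGFP-positive cells (vertical axis); each point is a gene, red where higher in both (586), blue where lower in both (1209). The named points include Nt5e at 1.72 and 4.05, Cxcr4 at -3.05 and -4.01 and Cd44 at -1.64 and -5.70.

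The comparison of rhoGFP-negative cells at P4 with nestinGFP-positive cells at P0 completes the 3 pairs of groups. Cd44 was 16.7-fold lower in the rhoGFP-negative cells, at 5.51 ± 0.38 against 9.57 ± 0.17 (log2, SD, n = 3), and the long non-coding RNA gene Rmst was 8.72-fold lower. In the rhoGFP-negative cells both genes, with Rmst at 5.14, lay below the median of all probe sets. There are no detection calls, so these folds are uncertain. Nt5e was 5.04-fold higher and Nrl 2.79-fold higher. In all, limma called 70 genes higher and 110 lower, 0.989% of those tested, and with the replicate number as a block 132 higher and 321 lower. Age, reporter line and sort gate differ together here.

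The 3 largest rises were in Nt5e (2.33 ± 0.39 SE, limma adjusted p = 0.0239), the secreted protease Htra1 (2.09 ± 0.38, 0.0304) and the cholesterol transporter Abca1 (2.02 ± 0.43, 0.0478). The 3 largest falls were in Cd44 (-4.06 ± 0.18, 2.42e-05), Rmst (-3.12 ± 0.29, 0.00541) and Tmem255a (-2.35 ± 0.25, 0.00541). With the mean of probe sets Nt5e (1.10, adjusted p = 0.0565) and Abca1 (1.06, 0.111) lost the call, and 0 of the 2 other probe sets of each was called. Cd44 (-2.20), Rmst (-2.03) and Tmem255a (-1.11) kept it at smaller differences. Rod genes rose in Abca4 (1.79 ± 0.23, limma adjusted p = 0.0107), the photoreceptor cadherin Cdhr1 (1.24 ± 0.21) and Unc119 (1.03), 3 of 33, or 6 adjusted over the list alone, with a median of 0.60 (camera adjusted p = 1.8e-07; adjusted p = 0.3 with an estimated correlation). Nrl (1.48 ± 0.27, limma adjusted p = 0.0314) and Crx (1.37 ± 0.29, limma adjusted p = 0.0478) were the 2 of 13 transcription factors called, or 3 adjusted over the list alone, with a median of 0.71 (camera adjusted p = 8.05e-09; adjusted p = 0.3 with an estimated correlation). Cone genes had a median of 0.35 (camera adjusted p = 0.0139; adjusted p = 0.3 with an estimated correlation) with 0 of 13 called by limma, 1 adjusted over the list alone and 5 with an unadjusted p below 0.05. Opn1sw was at 0.51 ± 0.34 (limma adjusted p = 0.491). The cone call was lost without rhoGFP-negative replicate 3 (median 0.23, adjusted p = 0.0713).

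Cell cycle genes fell in 5 of 51, Tyms (-1.47 ± 0.27), Cdt1 (-1.45 ± 0.30), Gins1 (-1.09), Ccne1 (-1.05) and Gins2 (-1.04), or in 35 adjusted over the list alone, with a median of -1.22 (camera adjusted p = 5.1e-26; adjusted p = 0.3 with an estimated correlation). Ccne1 held equal values on the rhoGFP-negative arrays (7.46, SD 0), which lowers its estimated spread. With the mean of probe sets Tyms was at -0.44 (adjusted p = 0.0809) and Cdt1 at -1.02 (0.0529), neither called. Of the 3 other probe sets of Tyms 0 were called and 1 had the opposite sign, and Cdt1 also lost its call after quantile normalization (0.0543). Within replicate numbers 1, 2 and 3 this median was -1.62, -1.71 and -0.23. Amacrine genes had a median of -0.56 with Lhx9 (-1.94) called (camera adjusted p = 6.49e-05; adjusted p = 0.3 with an estimated correlation). Ganglion cell genes had a median of -0.39 with Rbpms (-1.40) and Dlx1 (-1.33) called (camera adjusted p = 0.0017; adjusted p = 0.3 with an estimated correlation). Bipolar genes rose in Lhx4 (1.68 ± 0.18) and Pcp2 (1.45) and fell in Car8 (-1.67 ± 0.28; -1.02 with the mean of its probe sets), with a median of 0.20 (camera adjusted p = 0.00714; adjusted p = 0.3 with an estimated correlation). Progenitor genes had a median of -0.39 with 0 of 23 called by limma, 3 lower adjusted over the list alone and 10 with an unadjusted p below 0.05 (camera adjusted p = 0.0017; adjusted p = 0.503 with an estimated correlation). Nes was at 0.00 ± 0.18 (limma adjusted p = 0.998). Stress genes had a median of 0.36 with 0 of 21 called by limma, 1 adjusted over the list alone and 11 with an unadjusted p below 0.05 (camera adjusted p = 0.0017; adjusted p = 0.503 with an estimated correlation). Within replicate numbers 1, 2 and 3 the stress median was 0.70, -0.10 and 0.40, and the progenitor median -0.50, -0.64 and -0.04. Synapse genes had a median of 0.25 with Cacna2d4 (1.11) higher and Rims1 (-1.13) lower (camera adjusted p = 0.0431; adjusted p = 0.503 with an estimated correlation).

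The other lists were not called by camera in this comparison: adjusted p was 0.713 for neurogenic, 0.588 for horizontal, 0.698 for Müller genes with Apoe (1.09) higher, 0.101 for microglia, 0.0727 for pigment epithelium, 0.793 for cilium and 0.713 for glycolysis genes. The endothelial list had adjusted p = 0.793 (median 0.09, mean -0.06), the lens list 0.793 and the surface antigens 0.793 (median 0.05, mean -0.06), in which Nt5e rose and Cd44 and Itga6 (-1.40) fell. The erythrocyte list was at 0.0559, at 0.031 with the replicate number as a block, at 0.0429 with the mean of probe sets, and at 0.031, 0.0291 and 0.038 without rhoGFP-negative replicate 1 or 2 or nestinGFP-positive replicate 2. The microglia list was called with only the 6 arrays compared (adjusted p = 0.00649) and without rhoGFP-positive replicate 3 (0.00533). The pigment epithelium list was called with the mean of probe sets (0.0364) and without nestinGFP-positive replicate 3 (0.0481). The count of called genes fell to 8 higher and 11 lower without nestinGFP-positive replicate 2 and rose to 145 and 414 without rhoGFP-negative replicate 3. It was 11 and 20 without rhoGFP-negative replicate 1, 15 and 49 without its replicate 2. It was 127 and 200 without nestinGFP-positive replicate 1, 21 and 39 without its replicate 3. It was 35 and 40 or 44 and 68 without rhoGFP-positive replicate 2 or 3. Besides the cone list, the list calls lost with 1 array left out were those of progenitor genes (rhoGFP-negative replicate 2, 0.0506, or nestinGFP-positive replicate 1, 0.0679), bipolar genes (rhoGFP-negative replicate 1, 0.0583). The same held for stress genes (rhoGFP-negative replicate 1, 0.0551, or nestinGFP-positive replicate 3, 0.0695) and synapse genes (rhoGFP-negative replicate 1, 0.0837, or 2, 0.155, or nestinGFP-positive replicate 3, 0.167). The synapse call was also lost with arrays shifted to a common median (0.0564). Nt5e, Htra1, Abca1, Abca4, Cdhr1, Nrl, Crx, Tyms, Cdt1 and Car8 each lost the call in at least 1 of the 9 fits with 1 array left out, with adjusted p of up to 0.164 in Abca1 and Crx, whereas Cd44, Rmst, Tmem255a and Lhx4 kept it in all 9. Of the 10 genes that lost it, all but Abca4 also did so with only the 6 arrays compared (adjusted p from 0.0842 to 0.124).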

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

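The tests of a shared batch, of the pool of rhoGFP pups and of carry-over between sorts, and the fits without replicate 1 arrays or with the 18S signal as a covariate, and the carry-over shares with no upper limit on the signal, were chosen only after the values they bear on were seen.

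Outside the gene comparisons, the control probe sets for 18S ribosomal RNA carried a signal on the replicate 1 array of every group: 3.32 log2 units above the mean of replicates 2 and 3 in the rhoGFP-positive (3.317), 3.518 in the rhoGFP-negative and 2.126 in the nestinGFP-positive group. A feature of the rhoGFP replicate 1 pups alone is argued against, since the nestinGFP-positive replicate 1 array, from other pups, exceeded the higher of the other 2 of its group by 1.77, while these differed by 0.713. The replicate 1 arrays do not make the calls between the rhoGFP fractions either: without them 1861 of the 1988 calls stayed. The median absolute log2 difference of the called genes was 103% of its value, but these genes were chosen with the replicate 1 arrays included. Between rhoGFP-negative and nestinGFP-positive cells only 101 of the 180 calls stayed without these arrays, and 162 genes were called. Abca1, Car8, Cdt1, Crx, Htra1 and Tyms lost the call there. A shared processing batch of the replicate 1 arrays is a candidate explanation, as the nestinGFP-positive replicate 1 array deviated over genes together with both rhoGFP replicate 1 arrays (mean correlation 0.532). No biological explanation was tested.

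Between rhoGFP-negative and nestinGFP-positive cells the phototransduction list had a median of 0.60 with 3 of 33 genes called higher, and the transcription factor list 0.71 with 2 of 13, and camera called neither with an estimated correlation (adjusted p = 0.3 each; fry adjusted p = 0.06 for phototransduction and 0.013 for transcription factors). Under 3 other normalizations the phototransduction median stayed at 93.2% of its value or more. RMA had already quantile-normalized the values between arrays, so these normalizations could hardly move it. A normalization shift is therefore not decided by this test. Carry-over of GFP-positive cells into the negative sort, as the whole cause, would give the same implied share for every gene made by such cells alone. Genes also made by other cells, as Crx is in cones, need not have this share. Among genes called higher in rhoGFP-positive than nestinGFP-positive cells and below a log2 signal of 13, the median share was 27.9% ± 8.92 (SD over replicate numbers) for 5 transcription factors and 2.35% ± 0.458 for 23 phototransduction genes, a gap of 25.6 percentage points. With no upper limit on the signal the shares were 30.8% ± 6.99 for 8 and 3.50% ± 0.618 for 31 genes, a gap of 27.3 ± 7.23, though single genes overlap between the lists (Ankrd33 at 2.39%, Abca4 at 95.3% ± 6.97). The SD runs over same-numbered arrays, and the numbers were not taken to pair the GFP-positive fractions. Carry-over is argued against only as the whole cause for the transcription factors as a set, and not for the phototransduction genes. Single factors ran from 2.39% in Ankrd33 to 74.3% in Neurod1. Factors also made by other GFP-negative cells would show a higher share whether or not carry-over occurred, so the gap does not measure carry-over. Such expression was not tested and stays open. A carry-over of a few percent stays open, and so does the difference in age, with rods or their precursors in the negative fraction that carry little GFP, as an untested hypothesis.

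Cd44 was lower in both rhoGFP fractions than in nestinGFP-positive cells, by -5.70 and -4.06 log2 units. Cross-hybridisation of 1 probe set is argued against, since 2 of its 3 other probe sets were also called lower in both comparisons. A chromosome segment of other strain origin, or the transgene site, was not decided by its test. Among the 20 nearest measured genes on each side of Cd44, 1 was called between the rhoGFP-negative and nestinGFP-positive cells, against a median of 0 and a 95th percentile of 2 in 10000 random windows. Age and cell population stay open and untested.

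With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. Where the numbers were taken to pair the arrays, in both comparisons with the rhoGFP-negative cells, 4 of these part all 3 numbers, the real one among them, and the highest count was 0 both in the other 3 and in the 6 that keep arrays of 1 number together. The real split gave the most changed genes in each comparison, so 1 split of 10 reached its count: 1988 genes against at most 0 in the other splits for the rhoGFP fractions, 2838 against 0 for the GFP-positive fractions, and 180 against 0 for rhoGFP-negative against nestinGFP-positive cells. Every other split mixes arrays of both groups on each side, which puts the group difference into the spread. Their counts of 0 therefore set no level for the real counts.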

How the results depend on the processing

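The fits without the replicate 1 arrays, with the 18S signal as a covariate and without both replicate 3 rhoGFP arrays were chosen after the data were seen. Of the named genes in the 2 comparisons of the rhoGFP-positive fraction, 12 and 10 pairs of gene and alternative lost the call against 1184 and 1120 that did not change. In the third comparison 72 lost it against 256. With no minimum fold, 1830 genes were higher and 2587 lower between the rhoGFP fractions, 2906 and 3602 between the GFP-positive fractions. It gave 173 and 197 in the third comparison, and 1658 and 2353 in both comparisons of the rhoGFP-positive fraction, with 5 antigens higher in both. These counts move by construction. The third comparison gave 10 and 13 genes at an adjusted p below 0.01 and 13 and 15 with only its 6 arrays, which leaves fewer degrees of freedom. It gave 109 and 207 with the 18S covariate and 122 and 393 without the replicate 3 rhoGFP arrays, where the cause was not tested. With the replicate block its counts were 132 and 321. The block gave 667 and 1379 between the rhoGFP fractions and changed no other call there. Between the GFP-positive fractions the numbers were not taken to pair the arrays (correlations 0.52, -0.01 and 0.25). These values differ from those of the third comparison mainly in replicate 2. The block gave 925 and 1928, and pigment epithelium and glycolysis lists had an adjusted p of 0.0543. The antigens higher in both were 1 with the mean of probe sets and 1 without the replicate 3 rhoGFP arrays, as Nt5e lost its call; the cause was not tested. Camera called 15, 16 and 10 lists in the 3 comparisons, but 1, 1 and 0 with an estimated correlation, which rose to 0.731 in the cell cycle list. The cone list, with an estimate of 0.00907 against the preset 0.01, lost its calls too. The size of the correlation thus does not account for every loss. The cilium list, which kept its call in the first 2 comparisons, had an estimate of -0.0264. Fry, which does not compare a list with other genes, called 5 in the third comparison. There it did not call the phototransduction, cell cycle and ganglion (adjusted p = 0.06 each), amacrine (0.102), synapse (0.173), stress (0.176) and progenitor (0.252) lists, which camera called. Fry also did not call stress (0.0734) and microglia (0.267) between the rhoGFP fractions, nor microglia (0.0793) between the GFP-positive fractions. It also called lists that camera did not: bipolar (adjusted p = 0.0289), endothelial (0.0122), pigment epithelium (0.00254) and erythrocyte (0.0289) between the rhoGFP fractions, endothelial (0.0153) between the GFP-positive fractions, and erythrocyte (0.013) and cilium (0.013) in the third comparison. With each array left out in turn, higher and lower counts ran from 621 to 680 and 1182 to 1466 between the rhoGFP fractions, 883 to 970 and 1834 to 2004 between the GFP-positive fractions, 8 to 145 and 11 to 414 in the third comparison. They ran from 544 to 614 and 1051 to 1343 in both. Lists called ran from 13 to 16, 13 to 16 and 8 to 11, and antigens stayed at 2. Sign changes were those of Nes in the third comparison (-0.09204 with the mean of probe sets, -0.1807 without rhoGFP-negative replicate 3 or both replicate 3 rhoGFP arrays, -0.07185 without nestinGFP-positive replicate 1, from a value near 0, with a range of -0.1807 to 0.1095 with 1 array left out). Others were those of the microglia median between the rhoGFP fractions (-0.004592 without both replicate 3 rhoGFP arrays, one of which had the highest microglia values) and of the endothelial median between the GFP-positive fractions (-2.354 with dim genes left out, which tests fewer members and calls the list lower, adjusted p = 0.0117). Shifting arrays to a common median put the median of all genes at 0.111 between the GFP-positive fractions, against 0.0638. Signal over background limits genes such as Cd44, at 3.87 in the rhoGFP-positive cells.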

Other observations

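The genes in this part were chosen after their values were seen. Their counts need a call between rhoGFP-negative and nestinGFP-positive cells, and those 180 calls fell to 19 without nestinGFP-positive replicate 2 and rose to 559 without rhoGFP-negative replicate 3. With the replicate number as a block, which the counts below do not use, there were 453 calls. The rhoGFP-negative cells at P4 were highest of the 3 groups, with limma calls against both others, in 12 genes. Independent lists would share 5.12 genes highest and 3.97 genes lowest in these cells. Both comparisons use the same 3 rhoGFP-negative arrays, so part of the excess may come from them. The 12 genes include the LIM-homeobox gene Lhx4 (10.3 ± 0.27 log2, SD, n = 3, against 7.90 ± 0.12 in rhoGFP-positive and 8.59 ± 0.30 in nestinGFP-positive cells) and the bHLH factor Neurod2 (9.29 ± 0.30 against 7.91 ± 0.087 and 8.26 ± 0.45). Others were the matrix metalloprotease Mmp2 (8.80 ± 0.21 against 7.52 ± 0.29 and 6.87 ± 0.34) and the membrane protease St14 (10.6 ± 0.20 against 8.80 ± 0.21 and 8.98 ± 0.36). The same held for the non-canonical Notch ligand Dlk1 (7.53 ± 0.57 against 5.88 ± 0.22 and 5.88 ± 0.28) and the metallothionein Mt1 (9.78 ± 0.54 against 7.97 ± 0.42 and 8.23 ± 0.48). In 7 genes the rhoGFP-negative cells were lowest, among them the motor protein Myo7a (6.84 ± 0.28 against 8.53 ± 0.19 and 7.93 ± 0.24), the adhesion gene Dscam (7.17 ± 0.38 against 8.47 ± 0.25 and 8.31 ± 0.28) and the homeobox gene Pbx3 (7.74 ± 0.22 against 9.35 ± 0.32 and 9.21 ± 0.50).

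The nestinGFP-positive cells at P0 were highest against both rhoGFP fractions in 102 genes and lowest in 51, or in 94 and 48 without clone and model names. Among the former were the homeobox genes Gbx2 (6.99, against 4.57 in rhoGFP-positive and 4.74 in rhoGFP-negative cells) and Zfhx3 (10.6, against 7.55 and 8.41), the secreted guidance protein Reln (11.5, against 8.92 and 9.63), the microtubule protein Dcx (9.14, against 6.11 and 7.34) and the retinoic-acid-degrading enzyme Cyp26a1 (9.85, against 5.89 and 7.98). Among the latter were the photoreceptor genes Rd3 (7.62, against 11.5 and 8.83), Prcd (8.19, against 11.8 and 9.69) and Egflam (9.83, against 12.2 and 11.2), whose protein pikachurin lies at the photoreceptor ribbon synapse. Insm2 (8.17, against 9.51 and 9.83) and the activin subunit gene Inhbb (8.76, against 10.2 and 10.3) were lowest there too. Limma did not call either between the rhoGFP fractions, with log2 differences of -0.32 and -0.10.

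Of the 10092 probe sets without a single gene symbol, limma called 277 higher and 196 lower between the rhoGFP fractions, 374 and 396 between the GFP-positive fractions, and 11 and 13 between rhoGFP-negative and nestinGFP-positive cells.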
